A study of Drosophila melanogaster with 3 samples.

How the data were processed

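Anti-GFP ChIP-seq was performed on whole larvae of both sexes, at the wandering stage of the third instar, from a line carrying GFP-tagged sv, in 3 replicates that the labels number as biological replicates. Per the labels, chromatin was sonicated to a size range of 200 to 800. Per the deposited file manifests, the replicate peak lists and the pooled list were made against a shared control. The aligner, the peak caller, the threshold on reproducibility (IDR, the irreproducible discovery rate) and the antibody's source are not given in the sources used here. Read counts were not used here, so the depth per replicate is unknown and no counting interval is given. The control was not analysed here. The labels' descriptions name an antibody against GFP, while their antibody field names sv; the descriptions were followed, and an antibody against sv would also recover the native protein.

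The authors deposited, for each of 2 genome builds (dm6 and dm3), an optimal peak set thresholded by IDR, a relaxed list called on the alignments of all 3 replicates together, and a relaxed list for each replicate, deposited as input for IDR. The deposited signal value of each peak is the authors' own, and how it scales with the size of the library is not known here. In dm6 its median was 27.1 in the pooled relaxed list and 9.13 to 12.6 in the replicate lists. The signal was therefore used only within a list, to rank peaks and, at sv, as ratios between peaks of the same list. The deposited −log10 q-value reaches a ceiling in each list and was not used for ranking. The deposited summit offset, which per the file format counts bases from the start of the peak, gave the summit positions. In each build the optimal set was identical to the strongest peaks of the pooled list (3823 of 3823 in dm6 and 3666 of 3666 in dm3). Relaxed lists of 30000 peaks contain background, so shares in the replicates were taken from their strongest peaks, as many as the optimal set holds; the rank correlations, the peaks at sv, the pooled arm ratios and the classes of weak peaks used the relaxed lists beyond these.

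All positions are in dm6 and counted from 1. The genome sequence was the NCBI Release 6 assembly and the annotation that of Ensembl release 115 on BDGP6.54, both on the same coordinates as dm6. The comparisons used chromosome arms X, 2L, 2R, 3L, 3R and 4. A summit was assigned to 1 of 7 classes in the order promoter (within 500 bp of any annotated start, non-coding genes included), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, so coding sequence near a start counts as promoter. Shares were compared with 10000 circular shifts of all summits within each arm, which keep their spacing. Shifted summits can land in assembled heterochromatin, which holds few genes.

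Gene lists were compared with 10000 random lists of protein-coding genes drawn from the same 20 bins of gene span, with Benjamini-Hochberg adjustment over the 21 lists. The lists covered the sensory organ and bristle lineage, eye cone and pigment cells, bristle shaft, Notch, EGFR and Ras, ecdysone, Pax genes, imaginal discs, cytosolic ribosomal proteins, cuticle proteins, chemoreceptors, heat shock proteins, fat body, salivary gland, muscle, trachea, midgut, hemocytes, neurons, glia and testis. Of the listed names, 5 were matched through their FlyBase identifiers and 1, LabP, had no match. Motifs (17 consensus sequences, with 2 mismatches allowed in the long paired-domain consensus) and all 2080 6-mers were sought in windows of 101 bp at the summit and 1 kb to its right by the exact two-sided McNemar test. Pairs were left out where the control window lay within 250 bp of another optimal summit, which left 3642. Arm densities have 95% intervals from 2000 bootstrap draws of blocks of 500 kb. The threshold for an adjusted p was 0.05.

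The replicate grouping, the tests, the gene lists, the motifs and the alternatives were fixed before the data were examined, as was the rule for named genes. It takes sv, the gene with the nearest protein-coding start for each of the 10 strongest optimal peaks, and up to 3 members of each list with the highest-ranked summit. For lists with a lower share than matched lists it also takes up to 2 members without a summit in alphabetical order. Ogdh, Neb-cGP, CG13585, CG12402, Pal1, CG9119, CG42245, Bgb, Cals and the genes and families in the closing observations that no list holds were chosen after their values were seen.

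Alternatives were other summit distances and numbers of replicate peaks, promoter widths, gene assignments and matching, motif windows and backgrounds, the 1911 strongest optimal peaks, the dm3 lists, and leaving out each replicate. Without a replicate, the peak set was the optimal peaks found in both others. The dm3 lists were used only for the replicate comparisons, because no dm3 annotation was used here. The alternative that takes the strongest pooled peaks in place of the optimal set was identical to it and gave nothing to compare.

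The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots in matplotlib 3.10.9. The tests were tried on simulated data. With 3823 random summits, the promoter test passed an unadjusted threshold of 0.05 in 4.5% of 200 runs, and in 100% with 10% of the summits placed at starts. Random lists of 30 among the 13945 genes passed in 4% of 200 runs, and the motif test in 2.5% of 200 runs on random windows. Lists with 15 of 30 members replaced by genes with a summit, and windows with the site implanted in 2%, passed in 100%. The motif runs used random positions and the paired-domain core only. They do not cover the long consensus or the GC difference between the real summit and control windows.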

Results

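The data were peak lists from chromatin immunoprecipitation and sequencing (ChIP-seq) of the Drosophila transcription factor shaven (sv), tagged with GFP. The larvae came from a transgenic line that stably expresses sv isoform RD with GFP at its C-terminus, and per the sample descriptions chromatin was recovered with an antibody against GFP. sv is a Pax-family gene known for its roles in the cone and pigment cells of the eye and in the bristle lineage. Chromatin came from whole larvae of mixed sex, collected at the wandering stage of the third instar. There was 1 group of 3 biological replicates, with no second genotype, stage or treatment, so the comparisons the design allows are between the replicates and between the peaks and the rest of the genome. The optimal peak set held 3823 peaks in dm6, with signal values from 72.6 to 2018 and a median of 114. All 3823 peaks had the same −log10 q of 3.96, the highest value in that list, so only the signal ranked them. Each replicate list and the pooled list held 30000 peaks and included background, as input for the reproducibility filter. The read depth behind the lists is unknown.

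The strongest peaks recurred in all 3 replicates. The first peak in the optimal set and in every replicate list lay on chromosome 2L from 480817 to 481351, inside an intron of ush, a GATA cofactor gene, and 1387 bp upstream of the nearest protein-coding start, that of cbt, which encodes a zinc finger transcription factor. Its signal in the pooled data was 2018. The second, on 3L from 19590407 to 19590850, lay 99 bp upstream of CG14100 and ranked second in every replicate. The rest of the 10 strongest peaks had nearest starts at CG11050, CG4004, Chro, Ugalt, Lk6, CG1888, px and CG9663, and all 10 were found in all 3 replicates. Chro encodes the chromodomain protein Chromator, Ugalt a UDP-galactose transporter and Lk6 a protein kinase. Of these 10 summits, 5 were in promoters, 4 in introns and 1 in a non-coding exon.

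Among the 3823 strongest peaks of each replicate, a summit lay within 200 bp of 85.8% of the optimal summits in replicate 1, 81.1% in replicate 2 and 80.6% in replicate 3 (mean 82.5% ± 2.86, SD, n = 3). After circular shifts of the optimal summits, the highest share in any of 1000 shifts was 1.73%. All 3 replicates held 2315 of the optimal peaks (60.6%), at least 2 replicates held 3350 (87.6%), 1 replicate held 445 (11.6%) and none held 28 (0.732%). The share found in all 3 was 99.0% at ranks 1 to 956 of the optimal set, 89.3% at ranks 957 to 1912, 43.0% at ranks 1913 to 2867 and 10.9% at ranks 2868 to 3823. Each replicate list was cut at 3823 peaks too, so low-ranked optimal peaks can miss the cut by a small change of rank. Part of this fall is therefore built in. In the whole relaxed lists, which contain background, 99.5%, 98.6% and 98.2% of the optimal summits had a summit within 200 bp in replicates 1, 2 and 3. The optimal set came from the pooled reads, so the replicates are not independent of it. Across peaks, Spearman's rho of the replicate signals was 0.650 for replicates 1 and 2, 0.624 for 1 and 3, and 0.659 for 2 and 3, over 3708 to 3752 peaks, which are not independent of each other. No peak had the same summit and signal in any pair of replicates.

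**Figure D1:**
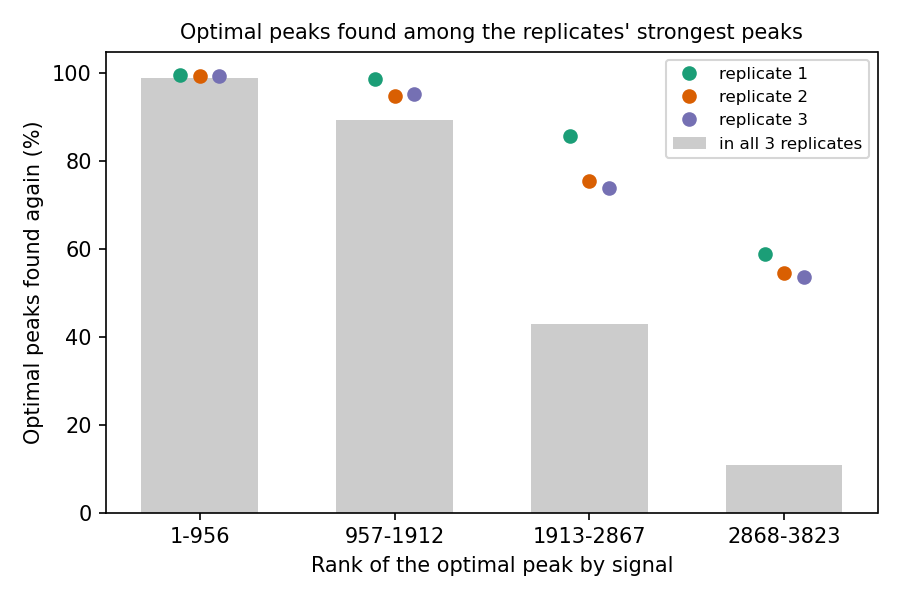
Share of optimal peaks (vertical axis, percent) with a summit within 200 bp among the 3823 strongest peaks of each replicate (points) and of all 3 replicates (bars), by rank of the optimal peak. The bars fall from 99.0% at ranks 1 to 956 to 10.9% at ranks 2868 to 3823.

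At the locus of the tagged gene, the optimal set held 1 peak, and it lay just past the 3' end of the gene. sv (FBgn0005561) spans positions 1088798 to 1113317 on the plus strand of chromosome 4. The peak ran from 1113191 to 1113514, with its summit at 1113339, which is 22 bp beyond the annotated end of sv and inside the 3' UTR of the neighbouring gene Cals (FBgn0039928), which runs on the minus strand from 1112874 to 1123357. With a signal of 481 it ranked 87 in the optimal set and was the strongest of the 13 optimal peaks on chromosome 4. No optimal summit lay within the gene itself.

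The same peak was the strongest on chromosome 4 in each replicate, at rank 158, 79 and 48, with signals of 171, 132 and 175. The next peak on that chromosome had a signal of 99.4, 53.4 and 61.7 in the same replicates. The pooled relaxed list held 22 peaks in sv and the 5 kb on either side. The next of these after the 3' peak had a signal of 49.7 and ranked 6379. These larvae also carry sv sequence on the transgene, whose extent is not given in the sources used here. Reads from the native copy and the transgene were not told apart.

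**Figure D2:**
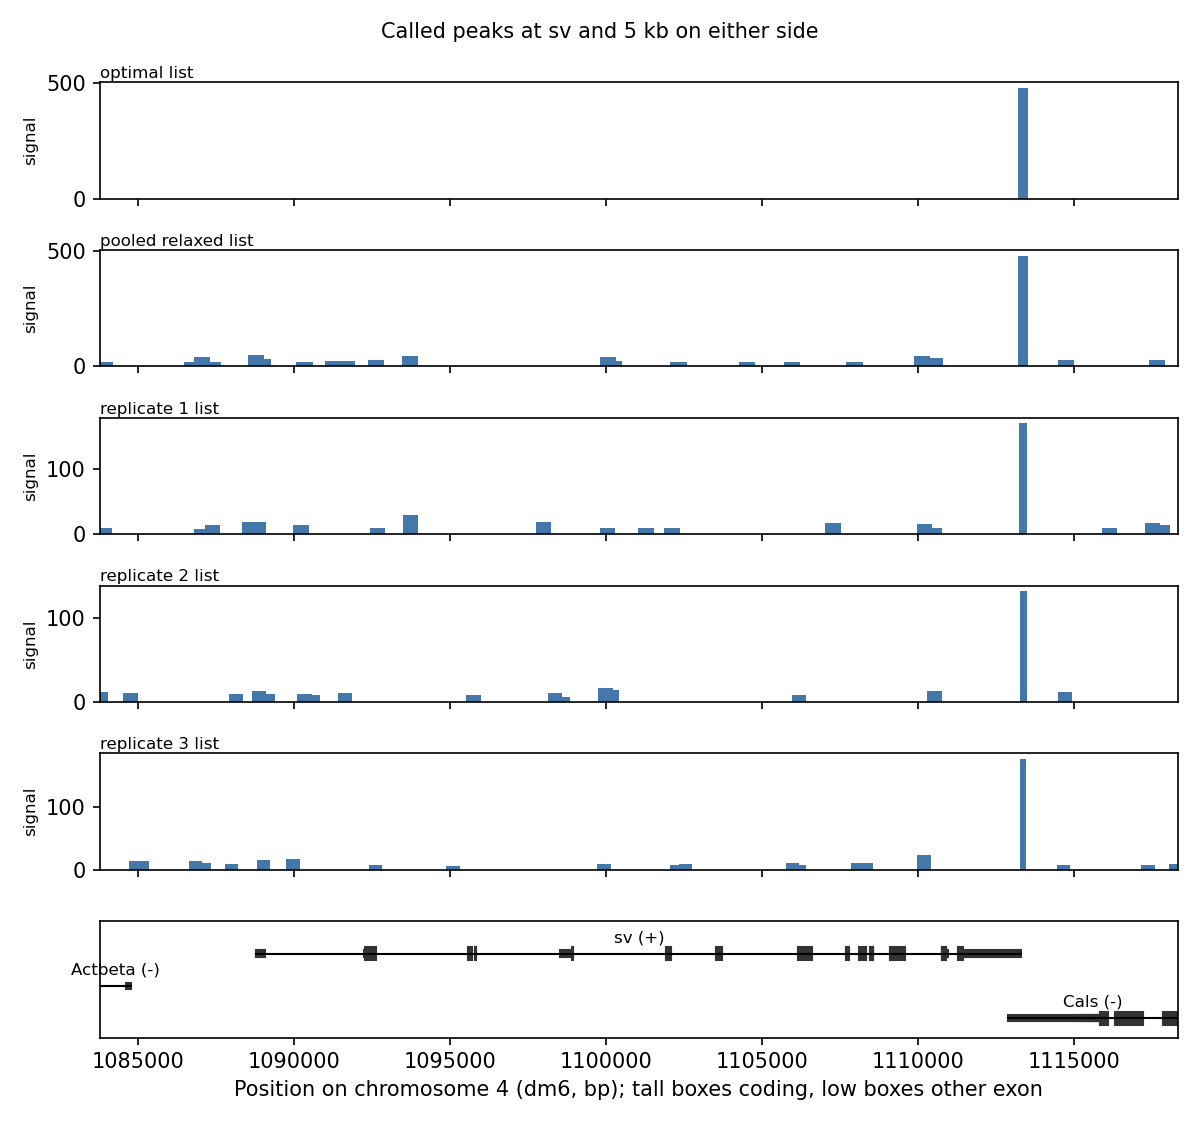
Called peaks at sv and 5 kb on either side on chromosome 4 (dm6 position in bp), drawn as bars from start to end with the deposited signal as height, for the optimal, pooled and replicate lists, each on its own vertical scale. Gene models with their strand are at the bottom, and the peak at the 3' end of sv has a signal of 481 in the optimal list.

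Most optimal summits lay at promoters, counted as within 500 bp of a start, and almost none in coding exons. Of the 3823 summits, 2250 (58.9%) lay within 500 bp of an annotated transcription start, against 13.6% after circular shifts, a 4.33-fold excess. Shifts kept inside the span of the optimal summits gave 14.9%, a 3.94-fold excess, and put 14.4% in coding exons. The 3823 strongest peaks of each replicate gave 58.4% ± 1.88 (SD, n = 3). With other promoter widths, the share of optimal summits was 43.2% within 200 bp of a start and 68.1% within 1000 bp. The shares of the 7 classes add up to the whole, so the promoter excess by itself lowers the others. Introns held 1105 summits (28.9%, against 39.5%) and intergenic sequence 382 (9.99%, against 27.2%). Coding exons further than 500 bp from a start held 6 summits (0.157%, against 13.1%; 0.0747% without replicate 2 and 0.0738% without replicate 3), and 3' UTRs held 26 (0.680%, against 5.05%).

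Each of these 5 classes differed from the shifts in a two-sided permutation test over circular shifts (adjusted p = 0.00028, from the smallest p that 10000 shifts can give, 0.0002). The 5' UTR held 17 summits (0.445%, against 0.777%, permutation adjusted p = 0.024), a call that ended in the 1911 strongest optimal peaks (adjusted p = 0.307) and without replicate 2 (adjusted p = 0.117). Other exons, those of non-coding transcripts, held 37 (0.968%, against 0.814%, permutation adjusted p = 0.369). Because the shares add up to the whole, the tests of the classes are not independent of each other. Among summits outside promoters, introns, 5' UTRs and other exons made up a larger part than among shifted summits outside promoters. Intergenic sequence, coding exons and 3' UTRs still made up a smaller part. This split was not tested. At ranks 15001 to 30000 of the pooled relaxed list, the promoter share was 21.7% and the coding exon share 15.3%.

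**Figure D3:**
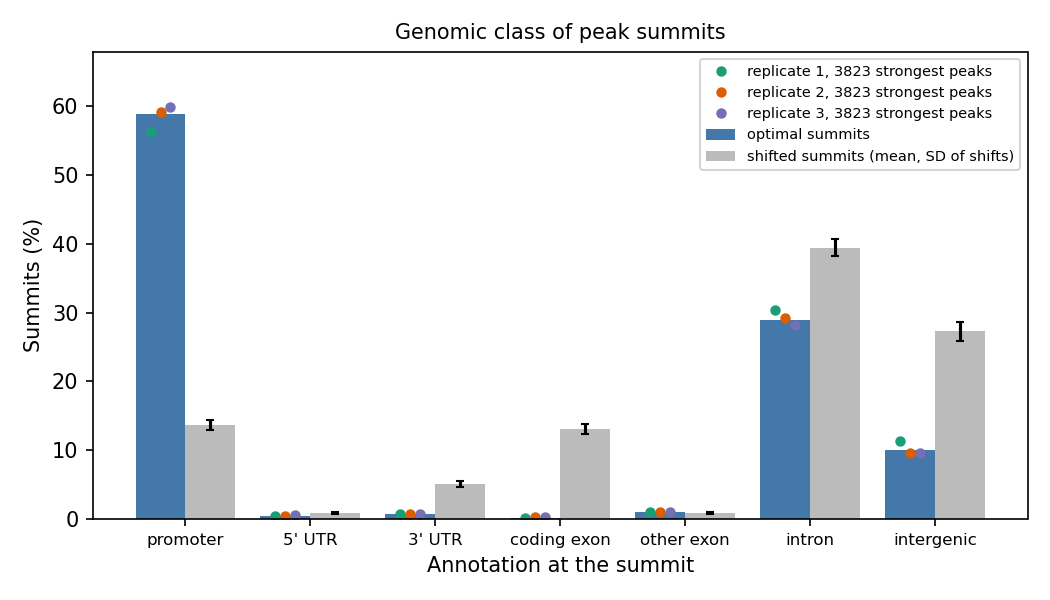
Share of summits (percent) in each annotation class for the optimal set (blue bars), for circularly shifted summits (grey bars, mean with the SD of 10000 shifts) and for the 3823 strongest peaks of each replicate (points). Promoters hold 58.9% of the optimal summits against 13.6% after shifting, and coding exons 0.157% against 13.1%.

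Genes for cytosolic ribosomal proteins held summits more often than matched genes. Of 88 such genes, 58 (65.9%) had an optimal summit in the gene body or 2 kb upstream, against 19.8% in gene lists matched for span, a 3.33-fold excess (two-sided permutation test, adjusted p = 0.0014), and 55 had it within 500 bp of a start. With summits within 10 kb counted, the excess was smaller (81.8%, against 54.4%, a ratio of 1.503, permutation adjusted p = 0.0014). The replicates gave 67.05% ± 6.01 (SD, n = 3). The strongest members were RpL7 (FBgn0005593; rank 102, signal 453, summit 20 bp downstream of its start), RpL34b (FBgn0037686; rank 124, signal 411) and RpS27 (FBgn0039300; rank 148, signal 385, summit 13 bp upstream). Among all 13945 protein-coding genes, 3751 (26.9%) had a summit by the same rule.

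Summits were rare at genes for cuticle proteins and chemoreceptors. Of 120 cuticle protein genes, 1 had a summit (0.833%, against 17.9%, permutation adjusted p = 0.0014). This was Cpr73D, and the nearest start to its summit was that of Ogdh, 587 bp away. Members of the Ccp84 cluster such as Ccp84Aa and Ccp84Ab had none. Of 179 odorant, gustatory and ionotropic receptor genes, 5 had a summit (2.79%, against 24.3%, permutation adjusted p = 0.0014). The strongest were at Or9a, Ir60e and Or88a, where the nearest starts were those of the neighbouring genes Neb-cGP, CG13585 and CG12402. Gr10a and Gr10b had none. With summits within 10 kb counted, the differences were smaller: 28 cuticle protein genes (23.3%, against 50.4%, a ratio of 0.463) and 56 receptor genes (31.3%, against 60.1%, a ratio of 0.520) had one. The counts of the main rule were 0 and 1 in the 1911 strongest optimal peaks, 0 and 3 (1.68%) without replicate 1, and 0 and 2 (1.12%) without replicate 3. Within 500 bp of a start they were 0 and 1. Genes of these families lie in clusters, which the permutation of single genes does not take into account.

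For the lists of the tissues in which sv is known to act, no difference from matched lists was detected. These lists are short, and the shares of their matched lists had an SD of 9.50 to 12.6 percentage points. Smaller differences could be missed, and in whole larvae the cells that express sv were not separated from the rest. Of 24 genes of the sensory organ and bristle lineage, 9 had a summit (37.5%, against 36.1%, permutation adjusted p = 1), and the 3 replicates gave 38.9% ± 4.81 (SD, n = 3). The strongest were elav, a neuronal RNA-binding protein gene, with a summit 251 bp upstream of its start at rank 79, N, which encodes the Notch receptor, at rank 170 in an intron, and numb, an asymmetric division determinant, 160 bp upstream of its start at rank 251. Of 23 genes of the eye cone and pigment cell programme, 8 had a summit (34.8%, against 45.2%, permutation adjusted p = 0.676), led by the ETS factor gene pnt (rank 500), kirre (rank 606), which encodes a cell adhesion protein, and aop (rank 1053), an ETS repressor gene, each in an intron. Of 15 bristle shaft and apical structure genes, 4 had one (26.7%, against 41.3%, permutation adjusted p = 0.645), among them sn, which encodes the actin-bundling protein fascin (rank 1092), dpy (rank 1478) and mwh (rank 2345, in an intron 519 bp from the start of CG9119). This last list had 3 (20%) without replicate 1 or replicate 2, and 2 (13.3%) without replicate 3.

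Signalling and regulatory genes held some strong summits without a detected excess for their lists. In the EGFR and Ras pathway, 11 of 18 genes had a summit (61.1%, against 41.6%, permutation adjusted p = 0.398; replicates 70.4% ± 6.42, SD, n = 3), led by Raf (rank 122) and aos (rank 257) in introns and spi, which encodes an EGFR ligand, 271 bp upstream of its start (rank 183). In the Notch pathway and E(spl) complex, 7 of 23 had one (30.4%, against 23.6%, permutation adjusted p = 0.840), N, neur (rank 532) and E(spl)malpha-BFM (rank 776) being the strongest. The ecdysone list had 9 of 19 (47.4%, against 44.2%, permutation adjusted p = 1), with intronic summits in the nuclear receptor genes Hr3 (rank 76) and Hr4 (rank 265) and a promoter summit at Eip75B (rank 607). The Pax family had 2 of 10 (20%, against 39.2%, permutation adjusted p = 0.645), Poxm (rank 661) and ey (rank 2588). The peak at rank 87, with its summit 22 bp past the end of sv, lies outside this rule and does not count for sv. Imaginal disc patterning genes had 8 of 27 (29.6%, against 45.2%, permutation adjusted p = 0.398), the strongest at Antp (rank 891), en (rank 1176) and dpp (rank 1443). Counting only summits within 500 bp of a start, that list had 1 of 27 (3.70%) and passed the threshold as lower (permutation adjusted p = 0.0262). Heat shock protein genes had 6 of 14 (42.9%, against 23.1%, permutation adjusted p = 0.398), with Hsp27 at rank 178, Hsp83 at 585 and Hsp26 at 977.

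For marker lists of other larval tissues no difference from matched lists was detected either, in a sample of whole larvae that holds all of these tissues. These lists are short too. The shares of their matched lists had an SD of 9.23 to 14.9 percentage points, so smaller differences could be missed. Muscle genes had 3 of 16, at Mef2 (rank 33, with the nearest start that of Pal1), sls (rank 439) and Tm1 (rank 3077, found in 1 replicate). Fat body genes had 3 of 13 (23.1%, against 32.5%), at the lipase gene bmm (rank 159), NLaz and Apoltp. Salivary gland genes had 1 of 13 (7.69%, against 16.9%), fkh (rank 1706). Hemocyte genes had 2 of 13 (15.4%, against 36.7%), ush (rank 1) and Pxn (rank 2764, 100 bp from the start of CG42245). The salivary gland and hemocyte counts were 0 and 2 without replicate 1, 1 and 1 without replicate 2, and 0 and 1 without replicate 3. Trachea genes had 6 of 11 (54.5%, against 43.6%), with grh (rank 638), trh (rank 1128) and sr (rank 2131). Neuron genes had 5 of 12 (41.7%, against 45.8%), with elav, ChAT (rank 759) and nSyb (rank 1453, 147 bp from the start of Bgb). Glia genes had 5 of 11 (45.5%, against 36.7%), with moody (rank 270), pnt and Gs2 (rank 842). Testis genes had 1 of 17 (5.88%, against 20.1%), bol (rank 1467). The trachea count fell to 4, 4 and 3 without replicates 1, 2 and 3, where the peak sets were also smaller. Midgut genes had 0 of 11 against 31.4% (permutation p = 0.025, adjusted p = 0.131); with summits within 10 kb counted, the adjusted p was 0.0472. Of the 21 lists, 3 passed the adjusted threshold, 1 higher and 2 lower.

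**Figure D4:**
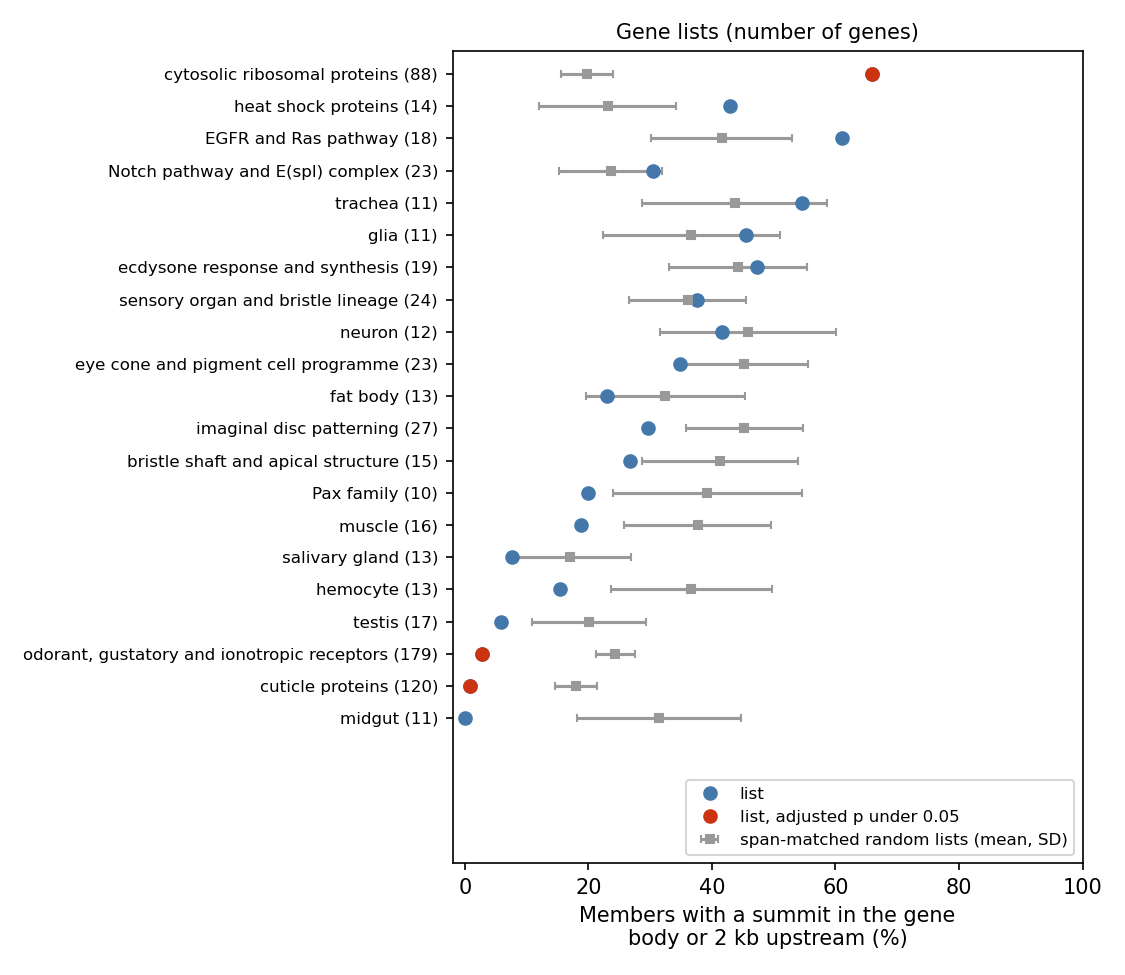
Share of the members of each gene list (rows, with the number of genes) that have an optimal summit in the gene body or 2 kb upstream (circles, percent), beside the mean and SD of 10000 random lists matched for gene span (squares). Red circles passed the adjusted threshold: ribosomal proteins at 65.9%, receptors at 2.79% and cuticle proteins at 0.833%.

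The promoter motifs DREF and motif 1 were more frequent at summits than in the windows beside them, though only at a small share of summits. The paired-domain consensus was not more frequent. The DREF site TATCGATA was present within 50 bp of 74 of 3642 summits (2.03%), against 7 windows centred 1 kb to the right (0.192%; exact two-sided McNemar test, adjusted p = 5.4e-14). Motif 1, the site of the promoter factor M1BP, was present at 45 summits (1.24%), against 4 (0.110%, exact McNemar adjusted p = 7.0e-09), and at 0.773% of summits in the 1911 strongest optimal peaks. With windows of 100 bp on each side, DREF was at 4.64% of summits against 0.632%, and motif 1 at 2.44% against 0.220%. Both excesses lay at the 2166 promoter summits, with DREF at 73 against 4 controls and motif 1 at 43 against 2. At the 1476 other summits the counts were 1 against 3 and 2 against 2. The control windows were not matched for promoter position, and promoters without a summit were not compared. An excess beyond that of promoters in general was therefore not tested. The long consensus of the Pax2 type of paired domain was present at 26 summits and 25 control windows (0.714% and 0.686%, exact McNemar p = 1), and its core GTCACGC at 14 and 27 (0.384% and 0.741%, p = 0.060, adjusted p = 0.113).

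The CA repeat (0.934%, against 2.55%, adjusted p = 9.1e-07) and the achaete-scute type of E-box (2.31%, against 4.20%, adjusted p = 2.1e-05) were less frequent at summits by the exact McNemar test; against shuffled windows of the same dinucleotide content, neither was lower. The Runx site, 1.87% against 2.99% (exact McNemar adjusted p = 0.0086), was no longer called against shuffled windows (adjusted p = 0.518), with the control to the left (0.0914) or with windows of 100 bp on each side (0.116). Of 2080 6-mers, 409 were more and 802 less frequent at summits, and base composition ran along with them. Summit windows had 35.1% GC against 43.1% in the control windows, 354 of the 409 (86.6%) had at most 2 G or C bases, and 523 of the 802 (65.2%) had at least 4. The largest ratios were those of CGATAG (6.95%, against 2.03%) and TATCGA (9.17%, against 3.54%), both overlapping the DREF site, and ACACTG (9.06%, against 3.65%).

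**Figure D5:**
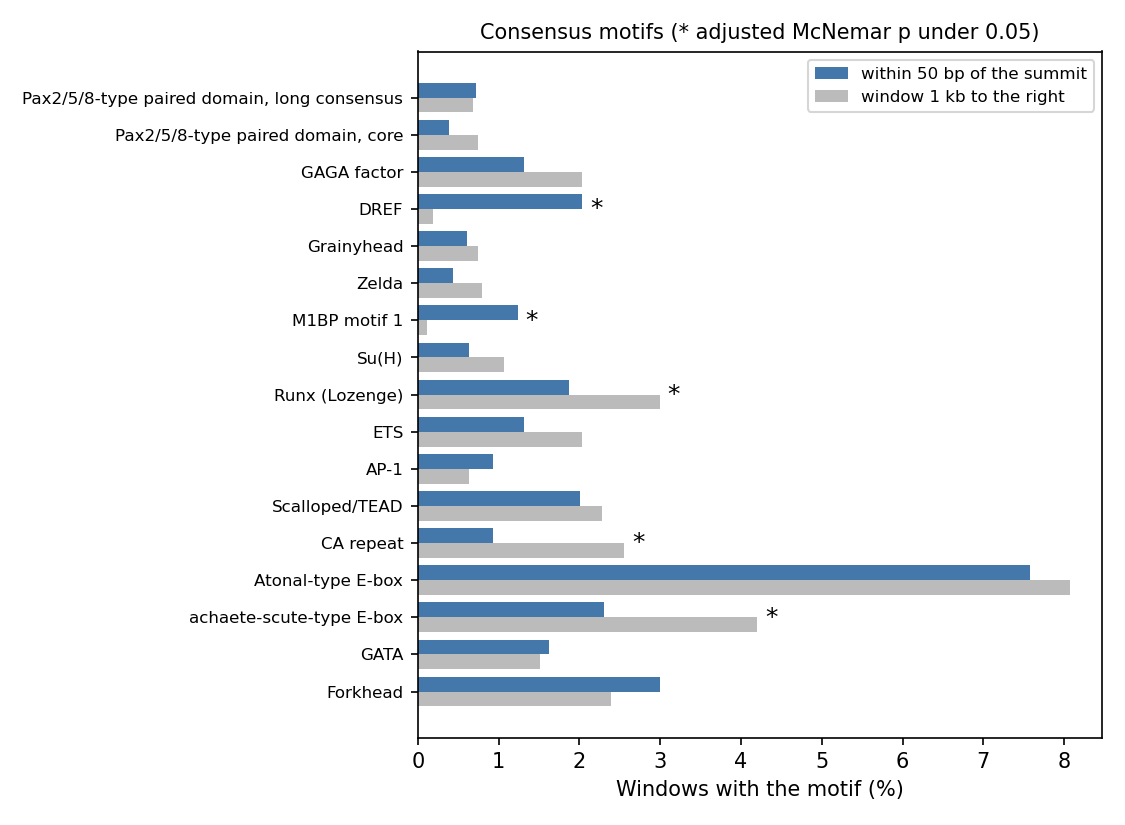
Share of windows (percent) that hold each consensus motif within 50 bp of the optimal summit (blue) and in the window 1 kb to the right (grey), over 3642 pairs; asterisks mark an adjusted exact McNemar p under 0.05. DREF reaches 2.03% against 0.192%, and the long paired-domain consensus 0.714% against 0.686%.

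Chromosome 4, the small and largely heterochromatic chromosome on which sv lies, had the lowest density of optimal summits. It held 13 summits, or 9.64 per Mb, against 28.6 per Mb over the 6 arms, a ratio of 0.338 (95% bootstrap interval 0.206 to 0.481), and the replicates gave 0.364 ± 0.0779 (SD, n = 3). In the pooled relaxed list its ratio was 1.14. The X chromosome had a ratio of 1.03 (0.875 to 1.18), and the ratios of 2L, 2R, 3L and 3R ran from 0.940 to 1.09, with intervals that all included 1.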

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

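The tests with shifts inside the span of the optimal summits and the correlations that leave out a replicate were chosen after the data were seen; the other alternatives were planned. The share of optimal peaks found in all 3 replicates, 60.6%, moved by more than the replicate SD with most settings: to 51.9% with summits within 100 bp, 64.6% with any overlap, 33.4% and 88.1% with 1911 and 7646 replicate peaks, 94.1% in the 1911 strongest optimal peaks, and 67.8% to 70.9% in the 2 replicates left when 1 was left out. Fewer replicates to satisfy raise this last share by construction. The mean rank correlation of 0.644 was 0.672 with summits within 100 bp and 0.624 to 0.659 for the pairs left without 1 replicate. The count of 1 optimal peak at sv fell to 0 within the gene only. The X chromosome ratio of 1.03 was 1.03 to 1.04 with 1 replicate left out. The numbers of classes, lists and 6-mers past the threshold stayed within 1.5 times their value, and the promoter excess and the calls for ribosomal, cuticle and receptor genes, DREF and M1BP held under every alternative run, the gene calls with smaller differences when summits within 10 kb were counted. Against dinucleotide shuffles, 6 motifs in place of 2 were called more frequent at summits. The ratios of 5 turned from below 1 to above 1: GAGA factor (1.28% of summits, exact McNemar adjusted p = 0.0242), ETS (1.28%, 0.0100), CA repeat (1.02%, 0.000665), the Atonal type of E-box (7.40%, 0.000665) and the achaete-scute type (2.33%, 0.0712). Of these, only the CA repeat went from a call as lower to a call as higher. The shuffle keeps the low GC of the summit windows, which the flanking control does not; the cause was otherwise not tested. Of the remaining comparisons with an alternative, 292 kept their call or value, 9 moved, 11 gained and 5 lost a call. The strongest pooled peaks were the optimal set itself, and the sv locus was not run in dm3. The unknown depth leaves open how many weak peaks a deeper library would add.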

Other observations

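The gene families, the promoter offsets, and the tests of housekeeping families, of highly transcribed tissues and of extra copies at sv were chosen after the results they concern had been seen; the tests of GC content, of the motif in subsets of summits and of repeated sequence were set down before their own results were seen.

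Among other housekeeping families, 1 passed the threshold. Of 73 mitochondrial ribosomal protein genes, 34 had a summit in the gene body or 2 kb upstream (46.6%, against 15.9% in lists matched for span, permutation adjusted p = 0.0011; replicates 49.3% ± 1.37, SD, n = 3), led by mRpL41 at rank 18, 132 bp from its start. Respiratory complex I genes had 14 of 40 (35.0%, against 19.9%, permutation adjusted p = 0.0579), translation initiation factor genes 17 of 44 (38.6%, against 27.5%, adjusted p = 0.181), vacuolar ATPase genes 12 of 33 (36.4%, against 24.2%, adjusted p = 0.181) and RNA polymerase subunit genes 11 of 31 (35.5%, against 21.97%, adjusted p = 0.175). Proteasome genes had 9 of 48 (18.8%, against 21.0%, permutation adjusted p = 0.856).

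Of 4 enzyme and odorant-binding families, 3 held summits less often than matched lists. Cytochrome P450 genes had 4 of 85 (4.71%, against 26.5%, permutation adjusted p = 0.0011), UDP-glycosyltransferase genes 1 of 35 (2.86%, against 25.6%, adjusted p = 0.00513), odorant-binding protein genes 1 of 51 (1.96%, against 15.8%, adjusted p = 0.0066) while Jonah and trypsin type protease genes had 0 of 27 (against 14.7%, permutation p = 0.0254, adjusted p = 0.0559). Genes of these families also lie in clusters, which the permutation of single genes does not take into account. The Hox genes had 3 of 8 (37.5%, against 47.2%, permutation adjusted p = 0.856). Promoter summits lay just upstream of the start: over 2159 summits within 500 bp of a protein-coding start, 85.4% were upstream of the nearest one, and 888 (41.1%) had a pair of divergent starts within 500 bp. Untested for difference, a summit lay within 500 bp of the start of 15 of 290 tRNA genes (5.17%), 19 of 269 snoRNA genes (7.06%), 157 of 3261 genes of other non-coding RNA (4.81%), 6 of 32 snRNA genes (18.75%) and 19.5% of protein-coding genes.

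The paired-domain consensus was no more frequent at summits than beside them, while DREF and M1BP sites were, though at promoter summits: outside promoters DREF was at 1 summit and 3 controls and M1BP at 2 and 2. At the 1476 summits outside promoters, 6 windows at summits and 10 controls held the long consensus (exact McNemar p = 0.454). The upper 95% bound on the ratio of discordant pairs was 1.82, which argues against a larger excess over the flanking windows there. Over all pairs the flanking windows had more GC than the summits, and shuffled windows were not tried outside promoters. Whether promoter summits hide a smaller excess, or one masked by base composition, therefore stays open. The core, at 3 and 4 with an upper bound of 4.43, also stays open. Dilution by weak peaks stays open, since the 500 strongest summits gave 3 and 3 (exact McNemar p = 1) with an upper bound of 7.47. In this smaller set DREF, at 5 and 1, and M1BP, at 2 and 0, did not pass either (exact McNemar p = 0.219 and 0.5). A candidate explanation is that summits mark housekeeping promoters in general: 5 families together had a ratio of 1.73 to matched lists (permutation p = 0.0002, the smallest possible), but 34 of their 86 genes with a summit were mitochondrial ribosomal, the other 4 families together had 1.36 (permutation p = 0.0156) and none of those 4 passed alone after adjustment. Reads gathering at the most transcribed genes also stay open. The fat body, muscle and salivary gland lists together had a ratio of 0.561 but a permutation p of 0.0686. These are lists of tissue markers, not chosen by measured expression, which was not used here. The cytosolic ribosomal protein list had a ratio of 3.33. No list from untagged larvae was used here to set binding of sv apart from either explanation.

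The scarcity of summits in coding exons, 0.157%, is not accounted for by the low GC of summits alone. Positions matched to the summits on arm and GC content fell in coding exons in 5.85% of cases (mean of 100 draws, lowest 4.94%), below the 13.1% of the circular shifts and above the observed share. GC content may therefore account for part of the difference. No biological explanation was tested.

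Of the 289 36-mers of the peak at the 3' end of sv, 0% occur again on the main arms. Other sequence and diverged copies were not searched, so the peak is shown free only of exact repeats on those arms. Its signal was 5.74, 8.21 and 7.48 times that of the next peak at sv in the 3 replicates, and 1.72, 2.47 and 2.84 times that of the next peak on chromosome 4. Extra copies of the locus on the transgene could raise reads there and cannot be told apart from binding, since the extent of the transgene is not given in the sources used here. The median signal of the other relaxed peaks at sv was 1.19, 1.22 and 1.02 times that of the rest of the chromosome in the replicates, below the 1.5 set for excluding copies but above 1, and 0.971 in the pooled list, while such peaks were 1.96 to 2.35 times as dense there in the replicates. Neither consensus of the paired domain was found in the 324 bp of the peak, and no biological explanation was tested.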
